A study of Mus musculus with 6 samples.

How the data were processed

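Lung cells sorted for GFP from aged (over 2 years) and young (12 to 16 weeks) Rosa26-mTmG mice, 11 days after infection with control or Dnmt1 hairpins, were sequenced as 10x Genomics 3' V3 libraries. The labels list 3 pools of GFP-positive cells and 3 hashtag libraries, which were not analysed here. The deposited table holds raw UMI counts for 32891 genes in 20916 cells. The labels name Cell Ranger 5.0.0, Scanpy 1.6.0, Seurat 3.0.2 and the GRCm38 (mm10) genome, without saying what each tool did. The lowest count of a cell was 502 UMIs, the highest number of genes 5998 and the highest mitochondrial share 4.998%, so the authors had filtered cells before deposit. The cell names mark 3 sets, which were used as libraries without being matched to replicate numbers, and give no age, hairpin or animal. Condition was not inferred from expression, since Dnmt1 is the target of the hairpins, so all comparisons of hairpin or age planned before the data were examined were left out.

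Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept, 7987, 8014 and 4842 cells in sets A, B and C. Scrublet called 9 cells (0.0430%). Whether the caller failed or few doublets were left after the authors' filter was not tested. No doublets were removed, and removing the highest 5% of scores in each set was an alternative. Clustering used scanpy 1.11.5 with igraph 0.11.9: counts were scaled per cell and log-transformed, 2000 variable genes were picked, 276 genes were held out of clustering, and 1945 genes (1935 for epithelial cells) went into 30 principal components, 15 neighbours and Leiden clusters at resolution 0.8. Epithelial clusters were clustered again. A marker was raised with a log2 fold of at least 1 and a UMI in at least 10% of the cells. Among all cells, a cluster took the name of the marker list with the highest mean log2 fold when this was at least 1, at least 3 markers and at least 50% of the list were raised, and no other list had more markers among its 10 leading genes. Within the epithelium, folds were taken against the other epithelial cells, and the list with the highest mean, AT2 aside, was considered when this was at least 0.75 with at least 3 markers raised. It gave the name when it was an epithelial list with at least 2 of its markers among the leading genes and more than any other list, and otherwise the cluster was left unnamed. Where no list was considered, the cluster was called AT2-like if the AT2 markers had a mean log2 fold of at least 3 over the non-epithelial cells, so AT2-like was the default name there, and the values were 5.14 to 5.62. A cycling and a dendritic-led cluster were called by at least 3 such genes among the leading genes. The naming rule was set after the clusters had been seen. The Ccl20-led cluster met the fold and raised conditions of the transitional list (mean log2 fold 2.04, against 1.24 in the transitional-like cluster) and stayed unnamed because none of those markers was among its leading genes. The club-like cluster also had all 10 ciliated markers raised. Another unnamed epithelial cluster, of 18 cells with a median of 12327.5 UMIs, had 10 alveolar macrophage markers raised. Its AT2 markers had a mean log2 fold of 4.34 over the non-epithelial cells, so doublets that Scrublet did not call may remain there. Its cells were counted as epithelial and entered no class comparison. Marker lists of 17 cell types and 19 tested lists held 455 genes, of which 11 were not in the table. The marker lists for ciliated, basal, neuroendocrine, smooth muscle or pericyte and mesothelial cells named no cluster at these settings, and the ciliated list named one at resolution 1.5, with 1000 genes and 10% mitochondrial UMIs and with the top doublet scores removed. Of the tested lists, the AT1, transitional and cell cycle lists were used in naming, and only Ctsh and Pcyt1a of the surfactant list were not, so 15 lists were tested. Symbols were looked up in GENCODE vM21, which lacked 362 of them.

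Levels are UMIs of a gene over all UMIs of a class in a set, scaled to a common total (CPM), with 95% exact Poisson intervals. Shares of cells have 95% exact Clopper-Pearson intervals. Both cover counting error alone. For a count of 0 the limit is 3 counts of the total. For shares of cells with a UMI and for cycling cells, each cell was thinned to 2000 UMIs, which left out 16, 19 and 4 AT2-like cells of sets A, B and C that were shallower. A cell was called cycling with at least 2 of 8 G2/M markers. Transcripts from other cells were read from AT2 genes in other classes.

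Classes were compared with edgeR 4.0.16 (R 4.3.3) on raw UMI counts summed per class and set: filterByExpr, TMM, robust quasi-likelihood fit with set as a block, quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The comparison of transitional-like with AT2-like cells was planned before the data were examined, and those of AT1-like and Ccl20-led cells were added afterwards. Genes used in clustering or held in the marker lists were left out of tested counts and lists. Genes that only lead a cluster, Ccl20 among them, were not. Lists were tested with limma 3.58.1: camera on log-CPM (prior count 2) with a preset correlation of 0.01 and with an estimated one, and fry, whose test asks whether the genes of a list move, on balance, one way. With an estimated correlation, camera takes its p from the few residual degrees of freedom of the summed counts. A list could then hardly pass, whatever its correlation, so a failure there does not decide against a call. Named genes followed a rule fixed in advance: Dnmt1, Nupr1 and Lcn2; the 8 genes with the largest rise and the 8 with the largest fall past the threshold, at 20 CPM or more in the higher class and with 1 direction in all sets, without Gm, Rik, ribosomal and mitochondrial genes; and up to 4 members of each list with the smallest p. On simulated data with 200 changed genes, the fit recovered 38.8% of 2-fold changes in the transitional-like comparison, 59.7% in AT1-like and 53.7% in Ccl20-led cells, with 1 false call of 81, 9 of 118 and 6 of 117.

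Sets were compared as values without a test: a gene differed when the ratio of CPM was at least 2 and it had at least 50 counts in the higher and 10 in the lower set. A pseudocount of 1 CPM was used only for the ratios of interferon genes between sets and of M cell genes between classes. Alternatives were no replicate block, no low-count filter, DESeq2 1.42.0, each set left out in turn, other depths and marker numbers for cycling cells, and CPM after thinning or the median over cells for sets. Added after the data had been seen were the resolutions 0.4 and 1.5 and the cell filters for the class comparisons, removal of doublet scores, AT2-like cells without the cluster led by Areg and Fosb, upper-quartile scaling and library totals alone. All alternatives for single genes and gene counts of the AT1-like and Ccl20-led comparisons, and leaving out sets for list tests, cycling cells and the differences between sets, were also added then. The other alternatives of the list tests were planned. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.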

Results

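RNA was counted in single cells sorted from the lungs of mice that carry the Rosa26-mTmG reporter, in which Cre switches a cell from tdTomato to GFP. The mice were aged (over 2 years) or young (12 to 16 weeks), and were infected to carry Cre with either a control hairpin (Ren713) or hairpins against Dnmt1, the enzyme that copies DNA methylation at replication. Lungs were taken 11 days after infection. The labels list 3 libraries of GFP-positive cells and 3 hashtag libraries. The count table holds 20916 cells in 3 sets, called sets A, B and C here. Set A held 8020 cells with 50946430 UMIs in total and a median of 6056 UMIs per cell. Set B held 8040 cells with 66833220 UMIs and a median of 7857, and set C held 4856 cells with 40056376 UMIs and a median of 7633.5. Nothing in the table gives the age, hairpin or animal of a cell, or says which set is which numbered replicate, and the hashtag data were not analysed here. The comparisons of Dnmt1 hairpins with the control, and of aged with young cells, were therefore not made. Each set pools animals and conditions, so the values below are given per set, as ranges over the 3 sets or as comparisons of cell classes within sets.

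The sorted cells were a mixture of epithelium and macrophages. Cells with the markers of alveolar type 2 cells (AT2), the surfactant-producing progenitors of the alveolus, made up 20.8% of set A (95% exact Clopper-Pearson interval 19.96 to 21.8), 18.6% of set B (17.7 to 19.4) and 31.9% of set C (30.6 to 33.2). Alveolar macrophage-like cells made up 16.8% of set A, 35.0% of set B and 29.1% of set C, and other myeloid-like cells 25.3%, 19.4% and 17.5%. All epithelial classes together reached 26.0%, 21.8% and 37.2%. Cells like alveolar type 1 (AT1), the flat gas-exchange cells, formed 1.26% to 2.23% of a set. Transitional-like cells, with 8 of 15 markers of cells between AT2 and AT1 raised, formed 0.496% to 1.18% of a set. Sprr1a, Lgals3, Sfn and Areg were the markers among their leading genes. An unnamed epithelial cluster that Ccl20, Serpinb1a, Ccl9, Msln and Spib led formed 0.724% to 2.04%. It had 11 of the transitional markers raised, against 8 in the transitional-like cluster, and was left unnamed because none of the 11 was among its leading genes. Among all cells, before the epithelium was clustered again, a cluster of 456 cells led by Scgb1a1, Ccl20, Msln and Spib took the club name. It had 6 of 9 club markers raised. The club gene Scgb1a1 gave 20.1, 751 and 40.5 CPM in Ccl20-led cells of sets A, B and C, against 58.0, 146 and 70.0 CPM in AT2-like cells. A cluster of mixed airway cells, named club-like (0.238% to 0.413%), T or NK-like cells (1.78% to 1.94%), B-like cells (1.61% to 2.07%), endothelial-like cells (0.847% to 1.65%), fibroblast-like cells (1.24% to 2.66%), neutrophil-like cells (0.289% to 1.24%) and a cycling cluster (1.28% to 2.65%) were the smaller classes. The club-like cluster also had all 10 ciliated markers raised, and at resolution 1.5 it gave way to 11, 12 and 10 club-like and 8, 8 and 11 ciliated-like cells in sets A, B and C. A cluster led by the dendritic cell genes Ccl22, Ccl17, Flt3 and Ccr7 formed 1.01% to 2.27%. Clusters 4 and 5 passed no marker list, cluster 4 with 11.4%, 10.6% and 6.18% of sets A, B and C, and cluster 5, which interferon genes led, with 8.36%, 0.474% and 0.454%. The sort and the pooling of animals set these shares in part, and some depended on the clustering. The median over sets for other myeloid-like cells was 19.4%, against 1.40% at resolution 0.4 and 7.33% at resolution 1.5. For transitional-like cells it was 0.799%, against 1.63% at resolution 1.5 and 1.64% with no cell filter, and no such class was named at resolution 0.4 or with the top doublet scores removed. For the Ccl20-led cluster it was 1.603%, against 0.989% at resolution 1.5 and 2.65% with 1000 genes and 10% mitochondrial UMIs.

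**Figure D1:**
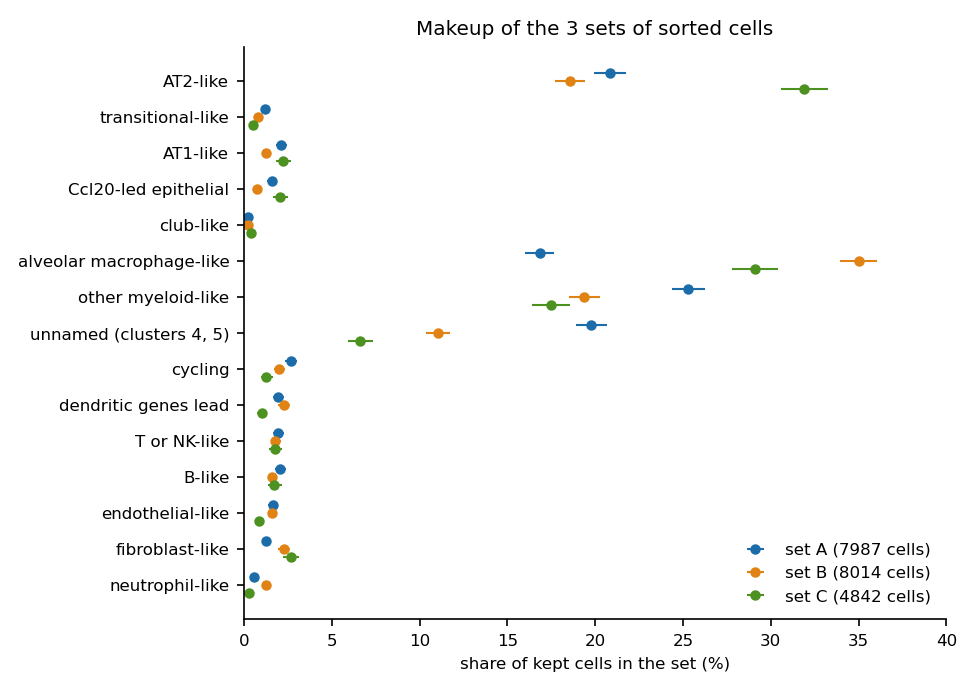
Share of kept cells of each class (x axis, percent) in sets A, B and C, with 95% exact Clopper-Pearson intervals as bars. AT2-like cells lay between 18.6% and 31.9%, and alveolar macrophage-like cells between 16.8% and 35.0%.

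The GFP message was most abundant in alveolar epithelium, and it was also found in fibroblast-like cells and macrophages above the level in lymphoid and endothelial cells. Transitional-like cells held 2003 to 2558 CPM of GFP (UMIs of a gene scaled to a common total of each sum), AT1-like cells 1353 to 1850, the Ccl20-led cluster 1304 to 1616 and AT2-like cells 1110 to 1504. Fibroblast-like cells held 432 to 1210 CPM of GFP, alveolar macrophage-like cells 533 to 672 CPM and other myeloid-like cells 439 to 541 CPM, against 105 to 251 CPM in endothelial-like and 227 to 309 CPM in T or NK-like cells. After each cell was thinned to 2000 UMIs, 86.1%, 89.0% and 82.0% of AT2-like cells of sets A, B and C held a GFP UMI, and 65.9%, 70.5% and 60.6% of alveolar macrophage-like cells did. In T or NK-like cells the share was 25.5%, 22.5% and 16.0%, and where their GFP came from was not tested. The surfactant message Sftpc was found in at least 97.6% of cells of every class listed, at 701.7 to 1484 CPM in other myeloid-like cells against 115660 to 116720 CPM in AT2-like cells. It was higher in endothelial-like (2765 to 14862 CPM), fibroblast-like (1570 to 12721) and neutrophil-like cells (3116 to 9587). AT1-like cells held 22425 to 37797 CPM of Sftpc and the Ccl20-led cluster 11928 to 23317 CPM. Transitional-like cells held 96183 to 110380 CPM, near the AT2-like level. How much of Sftpc and of other AT2 genes in these classes came from AT2-like cells was not tested. This limits the folds of AT2 genes in the class comparisons below.

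Dnmt1 was scarce in AT2-like cells and abundant in dividing cells, in sums that mix control and Dnmt1 hairpins. The share of each hairpin in a class is unknown. Class differences in Dnmt1, here and in the comparisons below, cannot be told apart from an effect of the hairpins. The same limit holds for every other gene compared between classes, and for age as well as hairpin. AT2-like cells held 10.1, 12.0 and 9.77 CPM of Dnmt1 in sets A, B and C (95% Poisson intervals cover counting error alone and are drawn in the plot of 4 genes by class), from 361 UMIs in all. The cycling cluster, in which the macrophage gene Chil3 reached 5441 to 11446 CPM and Sftpc 724 to 1117 CPM, held 171, 138 and 127 CPM. Uhrf1, the partner that brings Dnmt1 to replicated DNA, gave 117, 104 and 101 CPM in the cycling cluster and 1.87, 1.71 and 0.668 CPM in AT2-like cells. Alveolar macrophage-like cells held 29.1 to 46.2 CPM of Dnmt1. At 2000 UMIs per cell, a Dnmt1 UMI was found in 2.00%, 2.24% and 1.56% of AT2-like cells, so a lower level of the transcript was not detectable in single cells at this depth. The de novo methyltransferase Dnmt3a gave 60.2 to 77.4 CPM in AT2-like cells. Nupr1, a stress-induced chromatin protein, and Lcn2, the siderophore-binding protein lipocalin-2, were far higher in AT2-like cells than in macrophages: AT2-like cells held 324, 307 and 307 CPM of Nupr1 and 1674, 1140 and 1350 CPM of Lcn2, against 31.6 to 33.3 CPM of Nupr1 and 11.8 to 22.3 CPM of Lcn2 in alveolar macrophage-like cells. Nupr1 was also high in fibroblast-like cells, at 401 to 454 CPM, and Lcn2 in neutrophil-like cells, at 291 to 972 CPM. On GRCm38, as annotated in GENCODE vM21, Dnmt1 lies on chromosome 9 from 20907209 to 20959888, Nupr1 on chromosome 7 from 126623249 to 126630861, and Lcn2 on chromosome 2 from 32384633 to 32388252. All 3 are protein-coding genes on the minus strand.

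**Figure D2:**
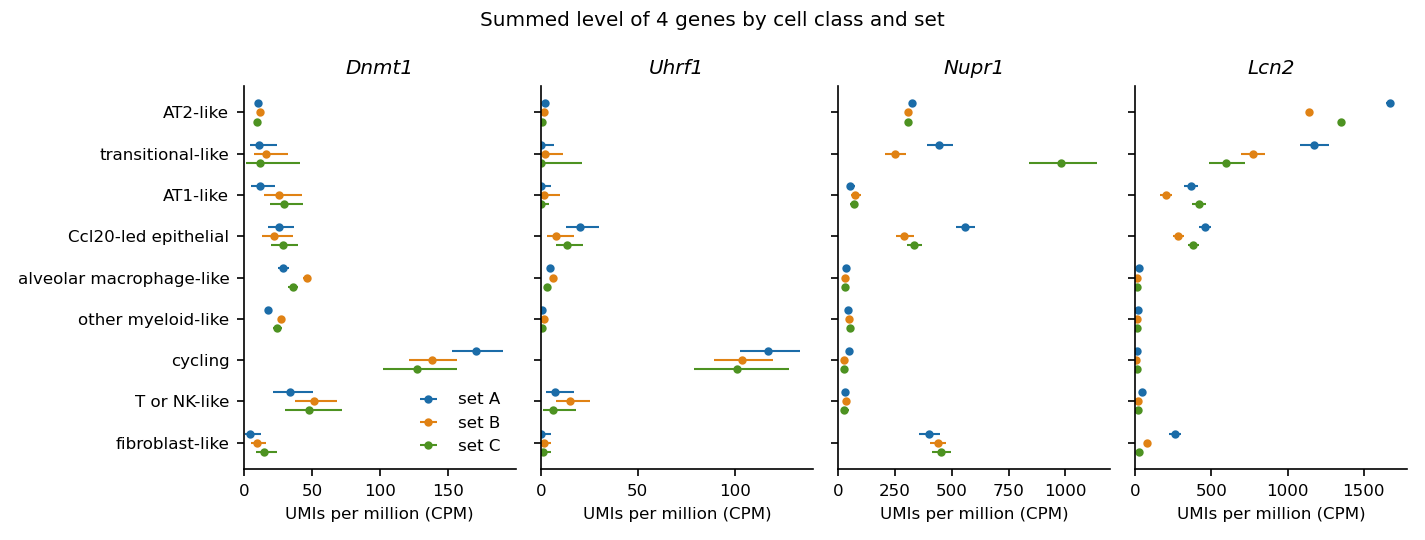
Summed level of Dnmt1, Uhrf1, Nupr1 and Lcn2 (x axis, CPM, from 0) by cell class in sets A, B and C, with 95% Poisson intervals as bars. Dnmt1 and Uhrf1 were highest in the cycling cluster, at 127 to 171 and 101 to 117 CPM, and Lcn2 lay at 1140 to 1674 CPM in AT2-like cells.

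Transitional-like cells had less of the lipid synthesis program than AT2-like cells, and more of some interferon, p53 and MHC class I genes. As lists, none of these 4 differences passed with an estimated correlation (camera, adjusted p = 0.40 to 0.403). That version has few degrees of freedom with 3 sets, so a failure there does not decide against a call. The estimated correlation lay below the preset 0.01 for interferon (-0.0174) and MHC class I (-0.0618). It lay above it for lipid synthesis (0.0460) and p53 targets (0.170). Of the 17 lipid synthesis genes tested, 14 fell and none rose: Elovl1 by 1.61 on the log2 scale (SE 0.13, n = 3 sets), Acaca by 1.11, Scd1 by 0.91 and Fasn by 0.87. Of 29 interferon genes, 10 rose and none fell, with Bst2 up 1.08 (SE 0.14) and Psmb8 up 0.76. Of 19 p53 targets, 7 rose and 1 fell, with Phlda3 up 2.04 (SE 0.31), Trp53inp1 up 1.00 and Gdf15 up 2.36, the last in 2 of the 3 sets. The AT2 growth factor receptor Fgfr2 fell by 1.11 and the alarmin Il33 by 1.85, while the inhibitor of NF-kB Nfkbia rose by 1.26. Without the replicate block several of these genes missed the threshold (edgeR), with an adjusted p of 0.137 for Scd1, 0.0818 for Fasn, 0.125 for Psmb8, 0.0512 for Trp53inp1, 0.123 for Gdf15 and 0.288 for Nfkbia. Gdf15 also missed it with DESeq2 (adjusted p = 0.241).

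The study's genes did not move together in this comparison. Lcn2 fell by 0.82 (SE 0.10; edgeR, Benjamini-Hochberg adjusted p = 3.7e-13), lower in 3 of 3 sets. Without the replicate block Lcn2 gave -0.80 and missed the threshold (adjusted p = 0.168). Dnmt1 gave a log2 fold change of 0.20 (adjusted p = 0.849), at 11.3, 16.6 and 11.5 CPM in transitional-like cells of sets A, B and C. Nupr1 gave 0.51 (adjusted p = 0.739), with 445, 251 and 981 CPM. Without set B the log2 fold change of Nupr1 was 0.93 (adjusted p = 1.2e-05). With clusters drawn at resolution 1.5, Dnmt1 passed at 0.89 (adjusted p = 0.0139) and Nupr1 at 0.62 (adjusted p = 0.0233). With 1000 genes and 10% mitochondrial UMIs as the cell filter, Dnmt1 passed at 1.06 (adjusted p = 0.00974) and Nupr1 at 1.09 (adjusted p = 1.6e-06), and with no cell filter Dnmt1 passed at 0.93 (adjusted p = 0.005). In the iron list 2 of 16 genes rose and 4 fell, the ferritin light chain Ftl1 up 0.79, transferrin (Trf) down with a log2 fold change of -1.92 and the metal importer Slc39a8 with -0.95. Of 15 ferroptosis and antioxidant genes 5 rose and 1 fell: the lipid peroxidase Gpx4 gave 0.73 and Srxn1 gave 2.06, while Acsl4, which makes peroxidation-prone lipids, gave -0.55. Without set A, Srxn1 missed the threshold (adjusted p = 0.157). Without the block Ftl1 (adjusted p = 0.146), Slc39a8 (0.0512), Gpx4 (0.242), Srxn1 (0.058) and Acsl4 (0.185) missed it, and with 1000 genes and 10% mitochondrial UMIs Gpx4 (0.0965) and Ftl1 (0.156) did. Of 10 MHC class I genes 3 rose, H2-D1 by 0.40, H2-K1 by 0.34 and H2-Q7 by 0.38. Without set A the folds were 0.41, 0.36 and 0.33, without set B 0.40, 0.37 and 0.44 and without the block 0.40, 0.34 and 0.40, about as large, but none passed: the adjusted p was 0.0979, 0.149 and 0.397, then 0.0801, 0.0787 and 0.145, and then 0.318, 0.527 and 0.378.

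By the rule set for single genes, the largest rises past the threshold in all 3 sets were Inf2 (2.40), Shisa4 (2.07), Srxn1, Phlda3, Hsd11b2 (1.96), Ankrd29 (1.96), Krt80 (1.94) and Rhobtb1 (1.80). Hsd11b2 missed the threshold without set A (adjusted p = 0.0667) and without set B (0.0539). The largest falls were Fabp12 (-2.48), Kcnj13 (-2.31), Ogfrl1 (-2.23), Popdc3 (-2.20), Slc24a4 (-2.14), Aass (-1.99), Ggt5 (-1.99) and Gpam (-1.98). Popdc3 missed the threshold without set A (adjusted p = 0.123), Aass without set A (0.115) and set B (0.0614), and Gpam without set C (0.0624). Without the block Popdc3 (adjusted p = 0.518), Gpam (0.263), Aass (0.0732) and Hsd11b2 (0.080) missed it, and DESeq2 gave no adjusted p for Popdc3, Aass, Hsd11b2, Inf2 and Ankrd29. Slc24a4 and Gpam also lead AT2-like clusters made mostly of set C. In all, 508 genes were higher and 831 lower of 11472 tested (edgeR quasi-likelihood with set as a block, false discovery rate 0.05), and 2621 had an unadjusted p under 0.05. Without the block the counts were 45 and 74, and with DESeq2 235 and 302. Without set A they were 171 and 374, and without set B 203 and 351. They rose to 1056 and 1102 at resolution 1.5, to 1347 and 1576 with 1000 genes and 10% mitochondrial UMIs, and to 1245 and 1345 with no cell filter. At resolution 0.4 and with the top doublet scores removed there was no transitional-like class to compare. With library totals alone as the scaling, 57.1% of called genes were higher, against 37.9%, and the median of all tested genes moved from -0.09 to 0.02 on the log2 scale.

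Over the lists, camera with a preset correlation called lipid synthesis lower (adjusted p = 4.1e-05), and interferon response (0.00027), p53 targets (0.00027), MHC class I (0.0055) and ferroptosis and antioxidant genes (0.0196) higher. With an estimated correlation none of the 5 calls passed, with adjusted p = 0.40 for lipid synthesis, interferon response and MHC class I, and adjusted p = 0.403 for p53 targets and the ferroptosis list. The ferroptosis call was also lost without set A (adjusted p = 0.0819) and without the block (0.0959). Adjusted over the list alone, 15 lipid synthesis genes fell, and 11 interferon genes, 8 p53 targets, 6 MHC class I genes and 5 ferroptosis genes rose. By fry, mitochondrially encoded genes (adjusted p = 0.0315), lipid synthesis and MHC class I (0.0347 each) passed. Interferon response (0.110), p53 targets and the ferroptosis list (0.148 each) did not. The other lists missed the threshold by camera, given here as genes higher and lower over all genes tested: progenitor regulators 0 and 3 of 12, dissociation stress 3 and 4 of 14, DNA methylation machinery 2 and 1 of 17, germline genes 0 and 2 of 4, imprinted genes 1 and 1 of 19, integrated stress response 1 and 2 of 12, MHC class II 2 and 0 of 9, mitochondrially encoded 0 and 5 of 13, and senescence and inflammation 6 and 1 of 15. For dissociation stress and imprinted genes the list median lay below 0 while the test pointed up.

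AT1-like cells had fewer transcripts of lipid synthesis and mitochondrially encoded genes than AT2-like cells, and more of interferon genes. No list call passed with an estimated correlation (camera, adjusted p = 0.540), a version with few degrees of freedom that could hardly pass. Of the 17 lipid synthesis genes 15 fell and none rose, with Elovl1 down by a log2 fold change of -2.07 (SE 0.12, n = 3 sets), Fasn by -2.06, Scd1 by -1.88 and Acly by -1.77. Nupr1 and Lcn2 fell, Nupr1 by -2.46 (SE 0.13; edgeR adjusted p = 7.1e-15) and Lcn2 by -2.31 (SE 0.12; adjusted p = 9.25e-14), each lower in 3 of 3 sets, and with them Trf (-2.27) and the transferrin receptor Tfrc (-1.73). Of 30 interferon genes 15 rose and none fell, led by Ifit2 (5.16), Ifit3 (3.70), Ifit1 (3.70) and Oasl2 (1.74). AT1-like cells of set A held 94.6 CPM of Isg15, against 17.2 in set B and 35.6 in set C.

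Dnmt1 was higher in AT1-like cells by 0.87 (SE 0.28; edgeR adjusted p = 0.0176, higher in 3 of 3 sets), but the call did not hold in all repeats. Without set B the fold was nearly unchanged at 0.86 and missed the threshold (adjusted p = 0.0562), without set C it fell to 0.52 (adjusted p = 0.347), and at resolution 0.4 it was 0.73 (adjusted p = 0.0584). Without the block Dnmt1 (adjusted p = 0.119) and Ptgs2 (0.0633) missed the threshold, and with DESeq2 Dnmt1 did (0.154). AT1-like cells had few Dnmt1 UMIs, 49 in all. Acsl4 (-1.53), Gclc (-1.61), the prostaglandin synthase Ptgs2 (-2.37) and the antioxidant regulator Nfe2l2 (-0.85) fell. The imprinted gene Nnat (3.08), the cell cycle inhibitor Cdkn2b (3.71), Phgr1 (3.63), Arxes2 (2.99) and Fstl3 (2.90) had the largest rises beside the Ifit genes. Kcnj2 (-3.18), Tex11 (-3.09), Anpep (-3.05), Fabp12 (-2.85), Il33 (-2.81), Tceanc (-2.67), Prmt8 (-2.62) and Ggt5 (-2.57) had the largest falls. Prmt8 also leads AT2-like clusters made mostly of set C. Tex11 is a meiotic gene of the germline list, and it held 40.9 CPM on average in AT2-like cells. Of 11449 genes tested, 1279 were higher and 1638 lower, and 3976 had an unadjusted p under 0.05. Without the block there were 476 and 560, and without set A 833 were higher. With library totals alone 68.9% of called genes were higher, against 43.8%, and the median of all tested genes moved from -0.03 to 0.19.

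Camera with a preset correlation called 5 lists in AT1-like cells: lipid synthesis (adjusted p = 2.7e-07), the mitochondrially encoded genes (4.1e-05, 10 of 13 lower), the Nupr1, lipocalin-2 and iron list (0.0074, 7 of 17 lower and 1 higher) and the ferroptosis and antioxidant list (0.0149, 7 of 15 lower and 1 higher) as lower, and interferon response as higher (3.5e-07). All 5 had an adjusted p = 0.540 with an estimated correlation, and the iron list missed the threshold without set A (adjusted p = 0.0924). Adjusted over the list alone, 15 lipid synthesis, 12 mitochondrial, 7 iron and 9 ferroptosis genes fell and 18 interferon genes rose. The lists that camera did not call were progenitor regulators (2 higher and 5 lower of 12), dissociation stress (1 and 6 of 14), DNA methylation machinery (4 and 4 of 17), germline genes (0 and 1 of 3), imprinted genes (3 and 4 of 19), integrated stress response (0 and 3 of 12), MHC class I (1 and 2 of 10), MHC class II (0 and 2 of 9), p53 targets (3 and 2 of 20), and senescence and inflammation (2 and 5 of 14). By fry 5 lists passed, all lower: mitochondrially encoded (adjusted p = 0.00129), ferroptosis (0.0157), lipid synthesis, iron and progenitor regulators (0.0372 each). Interferon response missed it by fry (adjusted p = 0.115). For imprinted genes the median lay below 0 while the test pointed up, and for senescence and inflammation the mean lay below 0 while the median and the test pointed up.

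The Ccl20-led epithelial cluster had more interferon and MHC class I transcripts than AT2-like cells and fewer of lipid synthesis. No list call passed with an estimated correlation (camera, adjusted p = 0.322 to 0.437), where few degrees of freedom made a pass unlikely. Of 30 interferon genes 26 rose with none lower, including the sensor Ddx58 (1.51), Oasl2 (2.59) and the immunoproteasome subunits Psmb8 (1.24) and Psmb9 (1.51). Of 10 MHC class I genes 8 rose, led by the peptide transporters Tap2 (1.73) and Tap1 (1.32). Of 17 lipid synthesis genes 16 fell, Elovl1 by -2.95 (SE 0.15, n = 3 sets), Scd1 by -2.36, Acaca by -2.08 and Hmgcs1 by -2.06. The cystine importer Slc7a11 (3.11) and Gclc (1.27), which act in glutathione synthesis, rose, while Acsl4 (-1.05) and Nfe2l2 (-0.73) fell. The alveolar regulator Nkx2-1 fell by 0.81 and Klf5 rose by 0.86.

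Lcn2 fell in this cluster by 2.20 (SE 0.11; edgeR adjusted p = 1.4e-11), while Nupr1 did not pass (adjusted p = 0.988). With clusters drawn at resolution 1.5, Nupr1 was lower by a log2 fold change of -1.37 (adjusted p = 6.1e-10), and Dnmt1 missed the threshold at 0.79 (adjusted p = 0.0681). With no cell filter Nupr1 was also lower, at -1.39 (adjusted p = 3.3e-09), and Dnmt1 missed it at 0.78 (adjusted p = 0.0706). With 1000 genes and 10% mitochondrial UMIs Nupr1 gave -0.72 (adjusted p = 8.9e-05). Dnmt1 rose by 1.00 (SE 0.22; adjusted p = 0.0011) and Uhrf1 by 3.04 (SE 0.45; adjusted p = 1.6e-05), each in 3 of 3 sets. Both genes were highest in the cycling cluster, and at 2000 UMIs per cell 2 of 127, 0 of 58 and 2 of 98 Ccl20-led cells of sets A, B and C (1.57%, 0% and 2.04%) had at least 2 G2/M markers. Of 20 imprinted genes 11 fell and none rose, including Plagl1 (-1.93) and Slc38a4 (-2.35), though the list call did not pass with an estimated correlation (camera, adjusted p = 0.322). Meg3, at 9.55 to 16.8 CPM in AT2-like cells, was listed at 0 UMIs in the cluster in each set, where 3 counts would be 2.38 to 3.94 CPM. The genes with the largest rises by the rule were Sox8 (8.57), Oit1 (7.81), Ptchd1 (7.06), Serpina1b (6.90), Camk2a (6.73), Lrrc26 (6.65) and Ccdc33 (6.38), all under 0.4 CPM on average in AT2-like cells. The rule also picks Ccl20, which is no finding since the cluster was singled out by it. The largest falls were Hkdc1 (-5.00), Slc24a4 (-4.52), Prmt8 (-4.28), Hykk (-3.98), Il33 (-3.62), Gpam (-3.50), Vldlr (-3.40) and Fabp12 (-3.37), of which Slc24a4, Prmt8 and Gpam also lead AT2-like clusters made mostly of set C. Of 11708 genes tested 2125 were higher and 2227 lower, and 5276 had an unadjusted p under 0.05. Without the block there were 1245 and 1277. With library totals alone 74.8% of called genes were higher, against 48.8%, and the median of all tested genes moved from -0.02 to 0.29. The cells of this cluster held a median of 9936 UMIs.

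**Figure D3:**
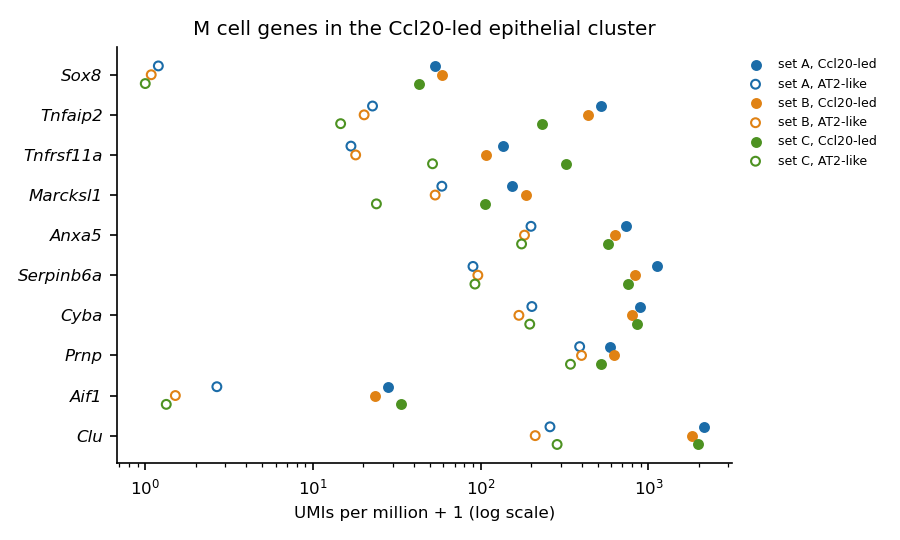
Summed level of genes of intestinal microfold (M) cells (x axis, CPM plus 1, log scale) in the Ccl20-led cluster and in AT2-like cells of sets A, B and C. Clu lay at 1810 to 2138 CPM in the cluster, against 210 to 284 CPM in AT2-like cells. The leading gene Spib, which is not drawn, lay at 378 to 464 CPM against 1.02 to 3.84 CPM.

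Camera with a preset correlation called lipid synthesis (adjusted p = 4.2e-09), mitochondrially encoded (2.5e-05, 12 of 13 lower) and imprinted genes (0.00177) lower, and interferon response (4.2e-09) and MHC class I (0.00063) higher in the Ccl20-led cluster. With an estimated correlation the adjusted p = 0.322 for interferon response, imprinted and mitochondrially encoded genes, adjusted p = 0.393 for lipid synthesis and adjusted p = 0.437 for MHC class I. Adjusted over the list alone the counts in these 5 lists were unchanged. The other lists had these genes higher and lower: progenitor regulators 2 and 7 of 12, dissociation stress 2 and 7 of 14, DNA methylation machinery 5 and 3 of 18, ferroptosis and antioxidant 3 and 5 of 15, germline genes 0 and 2 of 3, integrated stress response 1 and 4 of 12, MHC class II 2 and 1 of 9, the iron list 2 and 7 of 17, p53 targets 7 and 3 of 20, and senescence and inflammation 8 and 3 of 16, Ccl20 among the 8. For MHC class II the mean lay above 0 while the median and the test pointed down. By fry 8 lists passed. Lipid synthesis, mitochondrially encoded and imprinted genes were lower and MHC class I higher (adjusted p = 0.00939 each), and interferon response was higher (0.0203). Fry also passed 3 lists that camera did not call: p53 targets as higher (0.00939), and the iron list (0.0252) and progenitor regulators (0.0378) as lower.

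**Figure D4:**
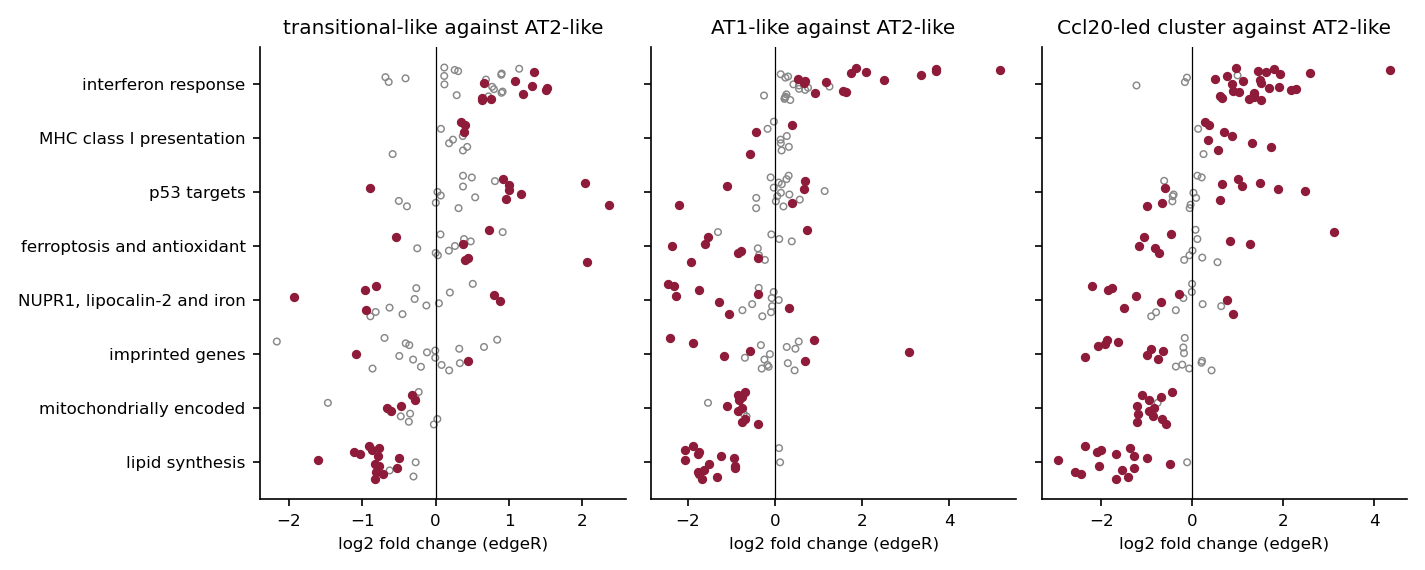
Fold change (x axis, log2, edgeR) of each tested member of 8 gene lists in transitional-like, AT1-like and Ccl20-led cells against AT2-like cells. Filled points passed the false discovery rate of 0.05, open points did not, vertical position within a list has no meaning, and genes at 0 UMIs in a class are not drawn. Lipid synthesis genes fell in all 3 comparisons (14, 15 and 16 of 17), and interferon genes rose (10 of 29, then 15 and 26 of 30).

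These 3 comparisons set sums of cells against each other, 1 sum per class and set, and the cells of both classes came from the same pools of animals and were assigned to classes on the same counts. Their p-values are therefore descriptive, and genes used for clustering or held in the marker lists were kept out of the counts. The age and hairpin makeup of each class is unknown. No fold between classes can be told apart from a difference in that makeup. Genes that only lead a cluster, such as Ccl20, were not kept out. AT2-like cells lay mostly in a different cluster in set C than in sets A and B. Transitional-like sums held 174275 to 533023 UMIs, AT1-like sums 582778 to 843541 and Ccl20-led sums 761242 to 1258080, against 10164100 to 11972000 UMIs for AT2-like sums.

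Few cells of the AT2-like clusters carried G2/M markers. The cycling cluster, with 212, 160 and 62 cells of sets A, B and C, was counted apart, so dividing AT2 cells placed in it are missing from these shares. At 2000 UMIs per cell, 1 of 1649 AT2-like cells of set A (0.0606%), 3 of 1470 of set B (0.204%) and 0 of 1541 of set C had at least 2 of the 8 G2/M markers, and 0 of 1541 allows a share of up to 0.239% by the exact interval. Pooled over sets this was 4 of 4660 cells, 0.0858% (exact interval 0.0234 to 0.22), and without set B 1 of 3190, 0.0313%. Unthinned, the AT2-like share was 0.511%.

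AT2-like cells of set C differed from those of sets A and B, which resembled each other. Of 10921 genes compared, 224 were at least 2-fold higher and 344 at least 2-fold lower in set C than in both other sets (5.20%), while sets A and B differed at this fold in 0.625% of 10726 genes. After thinning, 284 of 7161 genes differed in set C from both, and by the median over cells 36 of 1105. Against set A alone, set C differed in 1047 genes, and against set B alone in 761. In alveolar macrophage-like cells, 53 genes were higher and 26 lower in set C than in both others (0.813% of 9718). Most AT2-like cells of sets A and B lay in cluster 0, with 1639 and 1336 of its cells, and most of set C in cluster 2, with 1342. Among members of the fixed lists, chosen after their values were seen, Gpx4 gave 191, 189 and 86.9 CPM, Atf4, the transcription factor of the integrated stress response, 201, 178 and 69.0 CPM, Prdx1 664, 630 and 378 CPM and Ftl1 1202, 1103 and 693 CPM in AT2-like cells of sets A, B and C, whereas Nupr1 gave 324, 307 and 307 CPM. Il33 was higher in set C, at 702 CPM against 359 and 390. With 1 library per set and unknown makeup in age and hairpin, these differences have no test.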

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

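Signals outside the main measurement were found for the Cre transgene and for the sex-linked genes. Kept cells held 280 UMIs of Cre, a transgene that no comparison used. Alveolar macrophage-like cells held 122 of them (2.28 to 4.35 CPM) and other myeloid-like cells 75 (1.24 to 2.46 CPM), against 21 in AT2-like cells (0.394 to 0.919 CPM). T or NK-like and endothelial-like cells held 0, but their sums were too small for this to show a level below that of AT2-like cells. No library without Cre was used here to set a background.

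AT2-like cells came from animals of both sexes, and those of set C held few male cells. Of AT2-like cells, 38.9% in set A, 38.7% in set B and 7.25% in set C held UMIs of Y-linked genes and none of Xist. In alveolar macrophage-like cells the share was 43.8%, 44.6% and 19.09%. The share of AT2-like cells with Xist and no Y-linked UMI was 44.1%, 49.7% and 86.5%. Cells with neither, or with both, make up the rest, and depth limits both shares. The labels give no sex, so its relation to age and hairpin is unknown.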

How the results depend on the processing

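Of 2995 repeats of single-gene results, 2690 kept their side of the threshold, and their direction where they passed it. Of the rest, 252 no longer passed, 48 passed newly, 2 moved and 3 reversed. A change of direction was counted as reversed only where the main or the repeated fit passed. Of 162 repeats of summary values, 117 kept, 25 fell below, 9 rose past and 11 moved beyond the bound set for them. Except where stated, the cause was not tested. The resolutions, cell filters, doublet scores and scalings of the class comparisons, all alternatives for genes and gene counts in AT1-like and Ccl20-led cells, and leaving out sets for list tests, cycling cells and set differences were chosen after seeing the data.

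Without the replicate block, transitional-like cells had 45 genes higher and 74 lower (508 and 831 with it), AT1-like cells 476 and 560 (1279 and 1638) and Ccl20-led cells 1245 and 1277 (2125 and 2227). DESeq2 gave 235 and 302, 742 and 995, and 1325 and 1466. Without the low-count filter, 297 genes were higher in transitional-like and 852 in AT1-like cells. Library totals alone gave 814 higher in transitional-like cells, 2231 higher and 1008 lower in AT1-like cells, and 3860 and 1298 in Ccl20-led cells. That scaling moved the median log2 fold change of all tested genes from -0.09 to 0.02, from -0.03 to 0.19 and from -0.02 to 0.29.

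Transitional-like counts rose at resolution 1.5 (1056 higher), with 1000 genes and 10% mitochondrial UMIs (1347 and 1576) and with no cell filter (1245 and 1345). With each set left out in turn they ran from 171 to 539 higher and from 351 to 707 lower, and AT1-like genes higher from 833 to 1067, with fewer sums in each fit. Of the 5 lists called in each comparison, 0 passed with an estimated correlation in each, where few degrees of freedom made a pass unlikely. By fry, 3 lists passed in transitional-like, 5 in AT1-like and 8 in Ccl20-led cells. Interferon response was not among them in transitional-like and AT1-like cells.

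With 1000 genes and 10% mitochondrial UMIs, Saa3 in transitional-like cells gave a log2 fold change of -2.49 (edgeR adjusted p = 0.134), against 2.84, and in Ccl20-led cells Meg3 gave 0.26 (adjusted p = 0.916) and H2-Aa 0.14 (adjusted p = 0.322), each reversed.

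The median share of transitional-like cells was 0.799%, and 1.63% at resolution 1.5 and 1.64% with no cell filter. Ccl20-led cells made up 1.603%, and 2.65% with 1000 genes and 10% mitochondrial UMIs, 2.37% with the top doublet scores removed, 0.989% at resolution 1.5 and 0.96% with no cell filter. Other myeloid-like cells made up 19.4%, and 1.40% at resolution 0.4, 7.33% at resolution 1.5 and 8.92% with 1000 genes and 10% mitochondrial UMIs. Cycling AT2-like cells rose from 0.0858% to 0.511% unthinned, where deeper cells show more markers by construction. Genes that set C shifted in AT2-like cells numbered 568, and 284 after thinning and 36 by the median over cells, where fewer genes were compared, and 761 to 1047 with set A or B left out, where C must differ from 1 set.

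Not run were all alternatives for age and hairpin, which no cell carries. No transitional-like class was named at resolution 0.4 or with the doublet scores removed. The Leiden clusters gave no cycling AT2-like cells to count, the median of Dnmt1 over cells was 0, and the set C count has no value without set C. On simulated data 38.8% of 2-fold changes were recovered in the transitional-like comparison, so smaller changes there can be missed.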

Other observations

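The interferon test across cell classes, the matching of random lists on use in clustering, and the AT1-like and Ccl20-led comparisons were chosen after the results they concern had been seen.

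Germline and imprinted genes ranged widely in AT2-like cells, and the members named here were chosen after their values were seen. Dazl and H19 had 0 UMIs in AT2-like cells of all 3 sets, where 3 counts would be 0.251 to 0.295 CPM, and Igf2 had 0, 0 and 1 UMI. Meg3 gave 11.1, 9.55 and 16.8 CPM and Peg3 3.84, 3.41 and 3.68 CPM, while the germline gene Tex11 gave 32.8, 43.4 and 46.6 CPM. These sums mix control and Dnmt1 hairpins, so a change in a minority of cells would be diluted. Tet2 gave 50.1, 58.5 and 77.7 CPM and Tet3 54.2, 67.4 and 86.1 CPM in AT2-like cells, both above Dnmt1 (9.77 to 12.0 CPM).

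AT2-like cells of set C formed their own cluster. A difference in the sex of the animals may contribute: of set C AT2-like cells with Y-linked UMIs alone, 64.3% lay in that cluster, against 88.0% of those with Xist alone. Most male cells were in it too, but the gap between the kinds exceeded the bound set beforehand, so that test could not decide. Cells of the same kind differed by set. Of those with Xist alone, 3.40% in set A and 17.3% in set B lay in that cluster. Of those with Y-linked UMIs alone, 3.86% and 11.3% did. These values argue against sex alone as the source of the cluster, while a contribution of sex could neither be excluded nor shown. A shift of the whole library cannot be told apart either: 216 of the 568 shifted genes, those abundant enough in macrophages for the test, moved by a median of 0.33 (log2; bootstrap interval 0.27 to 0.46) in alveolar macrophage-like cells against 1.35 in AT2-like cells. That ratio, 0.241, lay just below the bound set against such a shift, and the bootstrap interval crossed that bound. Of the 216 genes, 172 moved the same way in alveolar macrophage-like cells. The tdTomato message, which was not part of that test, was highest in set C in every class. It lay at 405 CPM in AT2-like cells against 142 and 166, 290 in alveolar macrophage-like cells against 103 and 111, and 154 in T or NK-like cells against 47.3 and 52.3. As a single reporter gene it cannot decide between a shift of the library and a difference in the cells sorted. The mitochondrial gene mt-Nd3 was low in both classes of set C, while Lsmem1 was at 26.6 CPM in AT2-like cells of set C against 303 and 270 and nearly level in macrophages (43.2 against 50.1 and 51.9), both chosen after their values were seen. Age and hairpin makeup of the sets stay open, as untested.

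The unnamed interferon-led cluster 5 held 668 of its 728 cells (91.8%) from set A. A shift of the whole set A library would raise interferon genes in every class, but the median log2 ratio over AT2-like, T or NK-like, B-like and endothelial-like cells was 0.034. The rise was not limited to the cluster: the ratio was 1.24 in alveolar macrophage-like cells, 2.54 in the cycling cluster and 0.59 in AT1-like cells, against -0.14 in other myeloid-like and -0.34 in fibroblast-like cells. An AT2-like cluster of 299 cells, with the interferon gene Iigp1 among its 10 leading genes, held 68.2% of its cells from set A. Sets A, B and C held 1665, 1489 and 1545 AT2-like cells. The interferon list was not tested in that AT2-like cluster. Of the set A cells of cluster 5 with sex-linked UMIs of 1 kind, 0.974% had Y-linked UMIs alone, against 50.8% of the alveolar macrophage-like, other myeloid-like and cluster 4 cells of set A, as cells from few animals of 1 sex could give. The age, hairpin and health of those animals stay open, as untested.

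The Ccl20-led epithelial cluster did not look like doublets of epithelial and immune cells: the median level of 7 macrophage genes reached at most 2.91% of that in alveolar macrophage-like cells. A microfold (M) cell state is a candidate explanation: the median log2 ratio to AT2-like cells of 10 measured M cell genes was at least 2.72 in every set, above all 10000 random lists matched on expression. Of lists matched also on use in clustering, 4, 1 and 2 of 10000 were as high in sets A, B and C. The M cell gene Gp2 was listed at 0 in both classes, and 8 of the 10 genes had been used in clustering, so this is a hypothesis. No biological explanation from the design was tested.

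Each class comparison sets 3 sums against 3, and the 2 sums of a set are a pair. Of the 10 splits, 4 part all 3 pairs, the real one among them, and the other 6 put both sums of some set on 1 side. A share under 0.05 cannot be reached with either number. The real split was the 1 with as many genes in each: 1339 for transitional-like, 2917 for AT1-like and 4352 for Ccl20-led cells, and the highest of the other splits gave 0, among the 4 as among the 10.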
